A study of Mus musculus with 12 samples.

How the data were processed

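RNA was measured in 12 samples of alveolar macrophages, the resident phagocytes of the airspaces, in 4 groups of 3. Per the labels, the cells came from wild-type (control) or Lmp7 knockout mice of the C57Bl/6J strain, aged 8 to 12 weeks and housed specific pathogen-free. Lungs were lavaged with 8 washes of 1 ml, and the cells were left unpolarized (M0) or were given interleukin-4 (IL-4) at 20 ng/ml for up to 24 h (M2). Lmp7 is the protein name of Psmb8, the inducible catalytic beta5i subunit of the immunoproteasome. RNA was extracted with a column kit including DNase treatment, amplified with a whole-transcriptome kit and biotin-labelled, per the labels' protocols. Nothing says that the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

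The deposited values are of 2 kinds. The first table, per the file headers not normalized, holds for each of 25697 probes and each array an intensity and a detection p-value. These deposited intensities were whole numbers from -72 to 12659, so a background had been subtracted before deposit. The software and the genome build were not given in the sources used here. The columns of this table name the group and not the replicate number, so arrays are called a, b and c within a group, in the order of their column names. The second table holds the authors' processed intensities with replicate numbers. Its scale was linear, with a minimum of 16, a median of 86 in every column and a maximum of 11275, and its sorted columns differed by at most 63 units at any rank. In all 12 of its columns the best rank correlation with the first table was with a column of the same group (lowest 0.9999). Which background offset gave these values was not stated.

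Probes were named through the platform's gene annotation. Of the probes, 23978 had 1 gene symbol, 0 had several and 1719 had none, and the unnamed probes stayed out of the tests by gene. Gene order on chromosome 17 was taken from the RefSeq table of assembly GRCm38.p6, for names and neighbours only. Intensities were background-corrected with limma 3.58.1 in R 4.3.3 (normexp with the background estimated from the detection p-values, offset 16), quantile normalized and log2 transformed. Probes with a detection p under 0.05 on at least 3 of the 12 arrays were kept, which left 9200 probes. A gene was represented by its kept probe with the highest mean over all arrays, giving 6563 genes. A gene was called undetected in a group when this probe had no detection p under 0.05 on any array of the group.

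All 12 arrays entered a single linear model with 4 group means (lmFit, contrasts.fit and eBayes, 8 residual degrees of freedom). The 5 contrasts were the IL-4 response in each genotype, the genotype difference in M0 and in M2 cells, and the difference of the IL-4 responses (knockout response minus wild-type response). P-values were adjusted by Benjamini-Hochberg over the 6563 genes, and an adjusted p under 0.05 counted as past the threshold. Every adjusted p of a gene is from limma, and ± after a log2 difference is its standard error (SE) from this model, or the SD where stated. Values of a gene's dimmer probes and medians of lists carry no SE. Where a gene was undetected on every array of 1 group, the fold is a bound. It compares the mean of the brighter group with the mean, over the arrays of the dimmer group, of the higher of the gene's own value and the lowest value of a detected probe on that array. A gene detected on some arrays of its dimmer group keeps its model difference, which then includes values near background. List medians "at the bound" use these bounds and leave out genes undetected in both groups. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

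Before the data were examined, 36 gene lists were fixed, 9 of them markers of other cell types. The 27 lists with at least 5 measured genes were tested against all other genes with camera, two-sided, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 135 tests. Member counts are given over all genes and adjusted over the list alone. The rule for named genes was fixed at the same time. It took the 10 largest increases and the 10 largest decreases among genes past the threshold whose groups did not overlap, up to 4 members of each list past the threshold, a fixed set of proteasome subunits and M2 markers, and, where fewer than 10 genes passed, the 10 of smallest p. Il4ra, the IL-4 receptor chain in that set, was not analysed here.

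The steps were tested on simulated data with the real genes and their measured spread, in 10 simulations with 200 genes changed. For the genotype contrast in M0 cells, 28.2% of genes changed by 0.5 log2 units were recovered, 75.8% of those changed by 1 and 97.6% of those changed by 2, with 7.13% false calls. For the difference of the responses, the same shares were 8.51%, 48.7% and 91.2%, with 5.47% false calls. The M2 marker list, shifted by 0.4 log2 units, was called in 10 of 10 simulations of either contrast. The simulated genes varied independently of one another, so list calls were not tested under correlation between genes.

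The share of detected probes served as the depth of an array. It was between 25.5% and 34.2%, and the number of arrays limits the precision. Replicates within a group correlated at Pearson r of 0.952 to 0.980 across genes, and no pair was identical. Replicate numbers pair samples in 2 of the 4 comparisons of groups, as judged from the data alone. In the authors' values, the deviations from the group means of same-numbered samples correlated at 0.383, 0.249 and 0.116 between wild-type and knockout M0 cells, and at 0.363, 0.202 and 0.179 between knockout M0 and M2 cells. They also correlated, at 0.395, 0.309 and 0.138, between wild-type M0 and knockout M2 cells, which share neither genotype nor state. The arrays of lowest detected share came from these same groups, so pairing cannot be told apart from an effect of array quality.

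Alternatives were other background corrections, normalizations, probe filters and probe summaries, the authors' values, other variance models, a threshold of 0.10, only the groups compared, each array left out in turn, and camera with an estimated correlation or fry in its place. Chosen after seeing the data were fits with the replicate number as a block, a fit without the 3 arrays of lowest detected share and a fit with that share as a covariate. The block was fitted on the authors' values, since only their columns carry the number. The slide of each array was not given in the sources used here, so it was not used as a block.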

Results

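Transcript levels were measured on Illumina BeadArrays in alveolar macrophages lavaged from wild-type and Lmp7 knockout mice, unpolarized (M0) or polarized with IL-4 (M2), with 3 arrays in each of 4 groups. IL-4 is the cytokine that drives alternative, or M2, activation of macrophages, and the series asks how the loss of a working immunoproteasome bears on this polarization. Of 25697 probes, 31.2% ± 3.51 (SD, n = 3) were detected in wild-type M0, 30.6% ± 1.24 in wild-type M2, 30.9% ± 4.27 in knockout M0 and 29.6% ± 3.58 in knockout M2 cells. Knockout arrays differed from wild-type arrays by -0.71 percentage points in this share (two-sided exact permutation test, p = 0.688). Arrays a of wild-type M0, knockout M0 and knockout M2 cells had the lowest shares, 27.3%, 26.1% and 25.5%. The first principal component, with 44.1% of the variance, parted M0 from M2 arrays. Its mean score was -17.9 ± 1.58 (SD, n = 3) in wild-type M0 and -18.0 ± 0.880 in knockout M0 cells, against 14.8 ± 0.792 in wild-type M2 and 21.1 ± 2.70 in knockout M2 cells. The knockout M2 arrays all lay beyond the wild-type M2 arrays (two-sided exact permutation test, p = 0.1, the smallest that 3 against 3 arrays can give). The second component, with 13.8% of the variance, followed the detected share of the arrays (r = -0.904 over the 12 arrays). The third component, with 10.7% of the variance, parted the genotypes, with mean scores of -7.15 and -10.2 in wild-type M0 and M2 cells and 8.98 and 8.32 in the knockout groups.

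The targeted gene was examined first. Psmb8 encodes the beta5i subunit of the immunoproteasome, a proteasome form that cuts proteins into peptides for antigen presentation. Its only probe read 7.83, 7.53 and 8.04 log2 units on the wild-type M0 arrays and 7.96, 7.78 and 7.75 on the wild-type M2 arrays. It was undetected on all 6 knockout arrays, with values of 5.49, 5.36 and 5.67 in M0 and 5.79, 5.62 and 5.72 in M2 cells. Psmb8 was therefore at least 3.43-fold lower in knockout M0 cells (adjusted p = 1.833e-05) and at least 3.32-fold lower in knockout M2 cells (adjusted p = 3.098e-05), and every array matched the genotype of its label. Whether the probe lies in the deleted part of the gene is not known from the sources used here. IL-4 did not move Psmb8 past the threshold in wild-type cells (0.03 ± 0.141 log2, adjusted p = 0.927). Psmb9, the beta1i subunit encoded beside Psmb8, was higher in knockout M0 cells by 0.63 ± 0.116 log2 (adjusted p = 0.0358), a call lost under median scaling and without most single arrays. In M2 cells the difference was 0.45 ± 0.116 log2 and missed the threshold (adjusted p = 0.0812). Psmb10, the beta2i subunit, rose with IL-4 by 0.70 ± 0.0904 log2 in wild-type (adjusted p = 0.000461) and by 0.68 ± 0.0904 log2 in knockout cells (adjusted p = 0.000337). Its genotype differences of 0.27 ± 0.0904 in M0 and 0.25 ± 0.0904 log2 in M2 cells missed the threshold (adjusted p = 0.3001 and 0.240). Psmb5, the constitutive subunit that Psmb8 replaces, differed between genotypes by 0.39 ± 0.133 log2 in M0 and 0.33 ± 0.133 log2 in M2 cells, with adjusted p of 0.338 and 0.310.

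**Figure D1:**
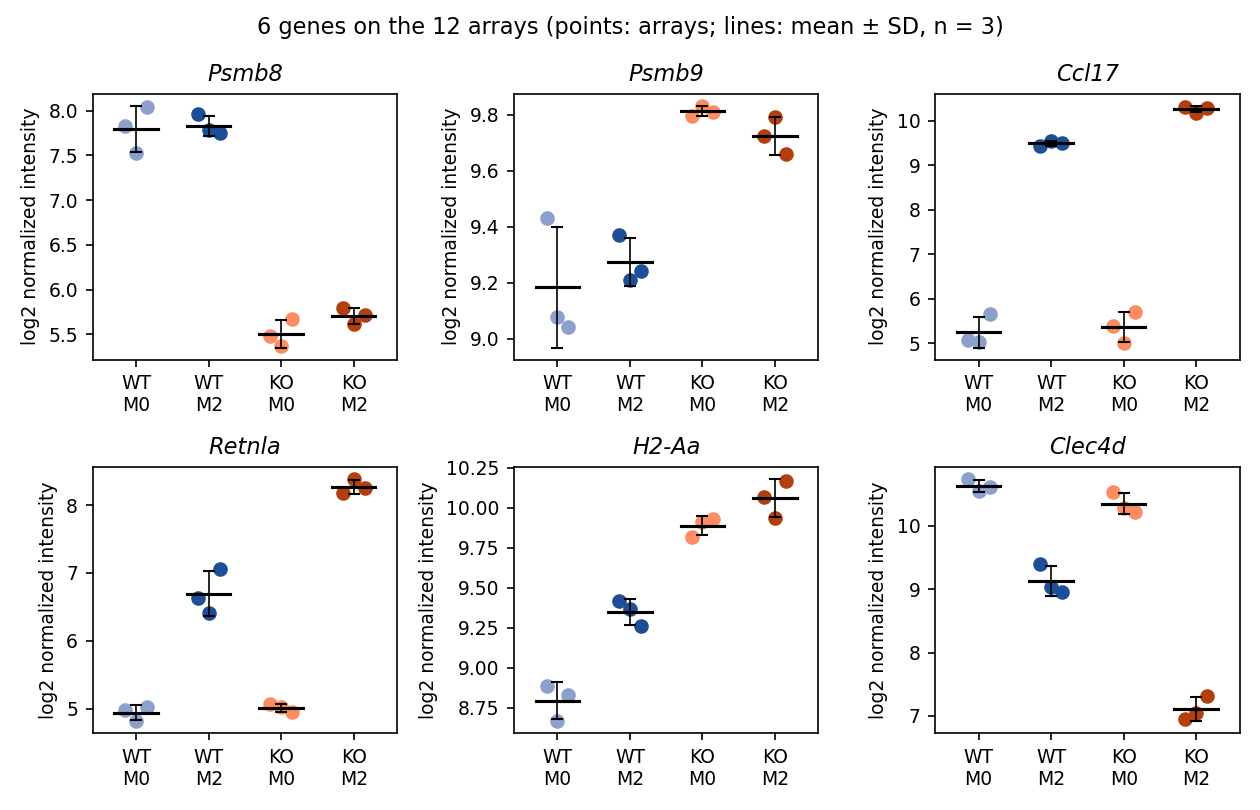
Log2 normalized intensity of 6 genes on the 12 arrays, by genotype (WT, wild-type; KO, Lmp7 knockout) and polarization, with points for arrays and lines for the mean ± SD of 3 arrays; each panel has its own vertical range. Psmb8 lay between 7.53 and 8.04 on the wild-type arrays and was undetected on all knockout arrays, Ccl17 and Retnla were undetected in M0 cells of both genotypes, and H2-Aa was higher and Clec4d after IL-4 lower in knockout cells.

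In wild-type macrophages, IL-4 raised the genes that define alternative activation. Rnase2a, an eosinophil-associated ribonuclease, was at least 10.6-fold higher (adjusted p = 5.583e-10), and Ccl17, a chemokine ligand of CCR4, at least 11.3-fold higher (adjusted p = 2.091e-07). Cish, a feedback inhibitor of cytokine receptor signalling, was at least 5.17-fold higher, the transcriptional coactivator Ppargc1b at least 3.34-fold, the transcription factor Irf4 at least 3.21-fold, the resistin-like molecule Retnla at least 1.63-fold and arginase 1 (Arg1) at least 1.62-fold. All of these were undetected in M0 cells. The chitinase-like protein Chil3 rose as well (1.62 ± 0.0961 log2), but its probe reached the ceiling of intensity in M2 cells, which may compress this value. Its other probes gave 1.29 and 1.96 log2. Mrc1, the mannose receptor, did not pass (0.22 ± 0.0940 log2, adjusted p = 0.152). Among the falls were those of Slc40a1, the iron exporter ferroportin (at least 5.23-fold lower), Apoc1, an apolipoprotein (-2.59 ± 0.242 log2), and the receptor Cxcr1 (at least 2.43-fold lower). In all, 1053 genes passed the threshold, 553 higher and 500 lower, and 108 and 92 of them changed by at least 2-fold in the model. The groups did not overlap for 34.1% of all genes, against 10% by chance. With median scaling in place of quantile normalization, 469 genes passed (285 higher, 184 lower).

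The M2 marker list stood furthest from the other genes in wild-type cells. Of its 23 measured members 16 rose and none fell (19 higher, adjusted over the list alone), with a median of 1.48 log2, or 0.93 with undetected genes at their bound (camera, adjusted p = 4.33e-20). Genes of the unfolded protein response followed, with 17 of 22 higher and 1 lower (18 and 2, adjusted over the list alone; median 0.70, 0.65 at the bound, adjusted p = 8.29e-11). Among them were the endoplasmic reticulum proteins Pdia4 (1.69 ± 0.142 log2), Creld2 (1.55 ± 0.155) and Hyou1 (1.44 ± 0.245). Of 34 oxidative phosphorylation genes 19 rose (24 over the list alone; median 0.42, adjusted p = 1.07e-11), with cytochrome c (Cycs) at 1.33 ± 0.227 and Ndufs1 at 0.74 ± 0.175 log2. Of 24 ribosome biogenesis and MYC target genes 12 rose (14 over the list alone; median 0.42, 0.33 at the bound, adjusted p = 1.86e-06), among them Myc itself, at least 2.21-fold, and Rrs1 (1.25 ± 0.186 log2). Of 30 cell cycle genes 12 rose (18 over the list alone; median 0.60, 0.52 at the bound, adjusted p = 6.56e-08), with the cyclin Ccnd2 at 1.24 ± 0.160 and the replication helicase subunit Mcm4 at 0.85 ± 0.159 log2. Of 9 genes of class II of the major histocompatibility complex (MHC) 6 rose (7 over the list alone; median 0.55, adjusted p = 1.04e-05), led by H2-DMb1 (1.2 ± 0.137 log2) and the invariant chain Cd74 (0.90 ± 0.145 log2). The constitutive proteasome list shifted as a whole by a median of 0.17 log2 (adjusted p = 0.00426), although Psma4 alone of 32 members passed (0.32 ± 0.0919 log2) and 0 did over the list alone.

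Of 12 classical (M1) inflammatory genes 6 rose with IL-4 in wild-type cells (6 over the list alone; median 0.43, adjusted p = 0.0013, but 0.0567 with an estimated correlation). They included the chemokines Ccl4 (2.59 ± 0.257 log2) and Ccl3 (1.51 ± 0.208 log2), the cytokine Il1b (at least 3.18-fold) and Tnfaip3, an inhibitor of NF-kB (1.03 ± 0.249 log2). Of 11 immediate early genes 6 rose (6 over the list alone; median 0.47, adjusted p = 0.00549, but 0.0621 with an estimated correlation), with Ier3 at 1.69 ± 0.168 and Fos at 0.88 ± 0.191 log2. Heat shock genes had 2 of 15 members higher (3 over the list alone; median 0.22, 0.16 at the bound, adjusted p = 0.0466, but 0.116 with an estimated correlation), Hsph1 at 0.61 ± 0.102 and Hspd1 at 0.48 ± 0.107 log2. The NRF2 oxidative stress list fell, with 7 of 19 lower and none higher (10 lower over the list alone; median -0.25, adjusted p = 8.32e-06). Its members included catalase (Cat, -0.64 ± 0.0973 log2) and Gclm, a subunit of the enzyme that starts glutathione synthesis (-0.67 ± 0.158 log2). Of 25 pattern recognition and phagocytic receptors 9 fell and 2 rose (9 and 2 over the list alone; median -0.25, -0.22 at the bound, adjusted p = 0.000716). The C-type lectin Clec4d (-1.50 ± 0.147 log2), the Fc receptor Fcgr4 (-1.37 ± 0.112) and the scavenger receptor Marco (-1.09 ± 0.121) fell, while the inhibitory Fc receptor Fcgr2b rose (1.2 ± 0.210). With an estimated correlation, 9 of the 12 list calls in wild-type cells held, all but the M1, immediate early and heat shock lists.

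In Lmp7 knockout macrophages, IL-4 again raised the M2 genes. Rnase2a was at least 15-fold higher, Ccl17 at least 19-fold, Cish at least 9.75-fold, Irf4 at least 5.4-fold, Retnla at least 4.75-fold, Ppargc1b at least 4.11-fold and Arg1 at least 2.33-fold (adjusted p of 8.866e-07 or below). The mitochondrial protein Chchd10 rose by 2.55 ± 0.154 log2. Slc40a1 was at least 6.69-fold lower. Clec4d (-3.24 ± 0.147 log2), Apoc1 (-2.96 ± 0.242), the transporter Flvcr2 (-2.87 ± 0.237) and Tnfaip2, a gene induced by tumour necrosis factor (-2.25 ± 0.138), fell too. In all, 1422 genes passed, 677 higher and 745 lower, 140 and 180 of them by at least 2-fold in the model, and the groups did not overlap for 36.4% of all genes, against 10% by chance. With median scaling 750 passed, 298 higher and 452 lower, so that the share of higher genes went from 47.6% to 39.7%, while in wild-type cells it went from 52.5% to 60.8%.

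Of the 23 M2 markers 18 rose in knockout cells (18 over the list alone; median 1.48 log2, or 1.22 with undetected genes at their bound; camera, adjusted p = 1.09e-19). Of 34 oxidative phosphorylation genes 32 rose (32 over the list alone; median 0.50, adjusted p = 1.86e-16), with Cycs at 1.75 ± 0.227, Atp5o at 1.46 ± 0.211 and Cox7a2 at 1.43 ± 0.237 log2. Of 22 unfolded protein response genes 16 rose and 1 fell (16 and 1 over the list alone; median 0.74, 0.67 at the bound, adjusted p = 1.24e-10), with Pdia4 at 2.13 ± 0.142 and Manf at 1.84 ± 0.115 log2. Of 24 ribosome biogenesis genes 12 rose (13 higher and 1 lower over the list alone; median 0.46, 0.45 at the bound, adjusted p = 1.04e-05), with Nop58 at 1.37 ± 0.194 log2, and of 30 cell cycle genes 11 rose (13 over the list alone; median 0.48, 0.36 at the bound, adjusted p = 8.5e-06, but 0.0795 with an estimated correlation), with Ccnd2 at 1.12 ± 0.160 log2. Of 9 MHC class II genes 5 rose (5 over the list alone; median 0.47, adjusted p = 0.000866, but 0.0926 with an estimated correlation), with H2-DMb1 at 1.21 ± 0.137 log2. Of 32 constitutive proteasome genes 5 rose (3 over the list alone; median 0.23, adjusted p = 0.00137), among them Psma4 (0.43 ± 0.0919 log2) and Psmb3 (0.42 ± 0.108 log2). Lower lists came next. Of 19 NRF2 genes 11 were lower (13 over the list alone; median -0.43, -0.31 at the bound, adjusted p = 1.57e-05), with the autophagy receptor Sqstm1 at -0.97 ± 0.155 log2. Of 25 pattern recognition genes 12 were lower and 2 higher (13 and 2 over the list alone; median -0.36, -0.31 at the bound, adjusted p = 1.38e-05), with the complement receptor C5ar1 at least 1.6-fold lower, the C-type lectin Clec4e at -1.42 ± 0.148 and Fcgr2b at 1.52 ± 0.210 log2. Of 33 autophagy and lysosome genes 7 were lower (7 over the list alone; median -0.14, -0.09 at the bound, adjusted p = 0.0323, but 0.117 with an estimated correlation), with Gabarapl1 at -0.93 ± 0.106 log2.

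The responses of both genotypes were compared gene by gene. No array is shared between them, and 433 genes rose and 406 fell in both (57.0 and 56.8 for independent lists), while 0 passed in opposite directions. The lists are not fully independent, since both rest on the same estimate of each gene's spread. Across the 6563 genes the responses correlated at r = 0.801 (Spearman 0.690); genes are not independent replicates. The orthogonal slope of the knockout on the wild-type response was 1.19. Of 1005 genes that rose on the mean of both responses 599 (59.6%) rose by more in knockout cells, and of 1053 that fell 752 (71.4%) fell by more. Genes past the threshold in a single genotype are not thereby shown to differ, for which the difference of the responses was tested.

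**Figure D2:**
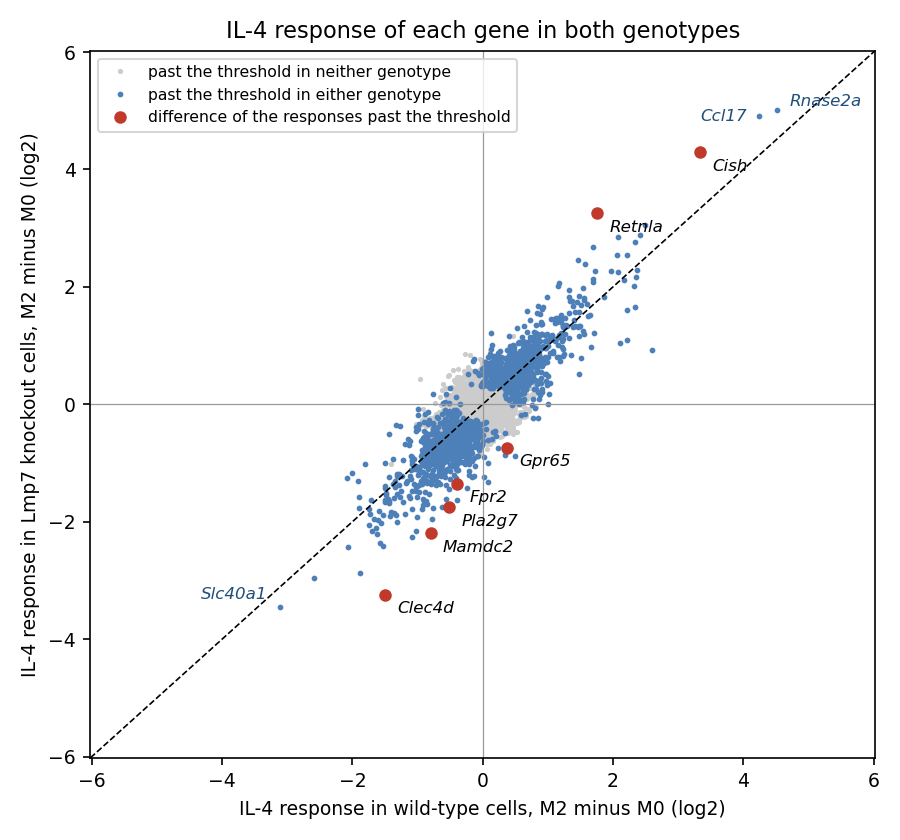
IL-4 response (M2 minus M0, log2) of each of 6563 genes in wild-type cells, horizontal, and knockout cells, vertical, with the line of equal response dashed. The 7 genes whose difference of responses passed the threshold are in red, with Retnla and Cish above the line and Clec4d, Mamdc2, Pla2g7, Gpr65 and Fpr2 below it.

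The difference of the IL-4 responses asks which genes respond to IL-4 in another measure without Lmp7. The M2 markers Retnla and Cish rose further in knockout cells, by 1.5 ± 0.212 log2 (adjusted p = 0.0312) and 0.96 ± 0.152 log2 (adjusted p = 0.04996). Both were undetected in M0 cells of either genotype, so their differences rest on the M2 levels. Negative differences were those of Clec4d (-1.74 ± 0.208 log2, adjusted p = 0.01496), the matrix glycoprotein Mamdc2 (-1.39 ± 0.173), Pla2g7, which encodes platelet-activating factor acetylhydrolase (-1.23 ± 0.156), the proton-sensing receptor Gpr65 (-1.10 ± 0.162) and the formyl peptide receptor Fpr2 (-0.95 ± 0.150). Clec4d fell with IL-4 in both genotypes, and further in knockout cells, so its response there was larger. Mamdc2 and Pla2g7 were higher in knockout M0 cells. The next genes by p, Tnfaip2 (-1.16 ± 0.195 log2), Clec4e (-1.18 ± 0.209) and Wfdc17 (-1.005 ± 0.176), had adjusted p of 0.0720, 0.0978 and 0.0935. Irf4, Arg1 and Ccl17 had differences of 0.78 ± 0.182, 0.56 ± 0.187 and 0.66 ± 0.270 log2, with adjusted p of 0.264, 0.630 and 0.725. By limma 7 genes passed in all and 436 had an unadjusted p under 0.05. The count fell to 0 without array b of knockout M0, array a of knockout M2 or array a of wild-type M2 cells (385, 410 and 362 genes at an unadjusted p under 0.05), and to 0 without the 3 arrays of lowest detected share (492 genes). Without the other arrays it was 2 (knockout M0 a), 3 (knockout M0 c, knockout M2 b, wild-type M0 a or wild-type M2 c), 1 (wild-type M0 c), 2 (wild-type M2 b), 5 (knockout M2 c) and 8 (wild-type M0 b), and the calls of Retnla and Cish were also lost with cyclic loess, with normexp at an offset of 50 and with the authors' values. Over all other settings run, Clec4d lost its call in 5, Mamdc2 and Pla2g7 in 8, Gpr65 in 12, Fpr2 in 14, Retnla in 17 and Cish in 20.

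By list, the M2 markers responded more in knockout cells, with 2 of 23 members past the threshold (6 over the list alone; median 0.36 log2; camera, adjusted p = 9.26e-07). No bound was set for this contrast. The median thus includes M0 values near background, since 7 of the 23 markers were undetected in M0 cells of both genotypes. The median was 0.28 to 0.41 log2 when any single array was left out, but with only probes detected at p under 0.01 on all 12 arrays the call was lost (adjusted p = 0.131, with 2.38e-07 to 0.131 over all settings run). That filter takes out markers undetected in M0 cells, Retnla and Cish among them, so a smaller list was tested. Oxidative phosphorylation genes responded more as a group, with 0 of 34 past the threshold singly (0 over the list alone; median 0.13, adjusted p = 6.08e-06). Cholesterol synthesis genes did not pass for IL-4 in either genotype (median -0.27 log2 in wild-type, -0.21 at the bound, and 0.17 in knockout cells, adjusted p = 0.104 and 0.0742), while their difference passed with 0 of 15 genes past it singly (3 over the list alone; median 0.41, adjusted p = 1.23e-08). Pattern recognition receptors responded with a larger fall, Clec4d passing of 25 (5 over the list alone; median -0.11, adjusted p = 0.00173). Over all genes the slope of the knockout on the wild-type response was 1.19, and 71.4% of genes that fell on the mean of both responses fell by more in knockout cells. Whether the pattern recognition or oxidative phosphorylation list differed beyond this general trend was not tested. M1 inflammatory genes had a lower response in knockout cells as a list, with 0 of 12 past the threshold (2 over the list alone; median -0.17, adjusted p = 0.0146, but 0.117 with an estimated correlation). The other 4 calls held with an estimated correlation. Median scaling moves the median of all genes in this contrast to -0.10 log2.

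In unpolarized cells, few genes parted the genotypes. Besides Psmb8, the largest decrease in knockout M0 cells was in H2-M2, a nonclassical MHC class I gene, undetected there and at least 11.7-fold lower (adjusted p = 1.833e-05). Also lower were Ch25h, the enzyme that makes 25-hydroxycholesterol (-1.85 ± 0.185 log2), the collagenase Mmp13 (-1.73 ± 0.205), the interleukin-7 receptor Il7r (-1.71 ± 0.191) and Marco (-1.27 ± 0.121). Higher were Mamdc2 (1.55 ± 0.122 log2), Pla2g7 (1.42 ± 0.110), the mitochondrial chaperone-related protein Dnajc15 (1.41 ± 0.120) and the MHC class II gene H2-Aa (1.09 ± 0.104). Complement C1qb (at least 1.64-fold), the chemokine receptor Cxcr2 (at least 1.80-fold) and apolipoprotein E (Apoe, 1.35 ± 0.253 log2, adjusted p = 0.0369) were also higher. By limma 45 genes passed, 25 higher and 20 lower, and the groups did not overlap for 14.8% of all genes, against 10% by chance. Of the genes named here, Psmb8, H2-M2, Ch25h, Mmp13, Il7r, Marco, Mamdc2, Pla2g7, Dnajc15 and H2-Aa passed in every other setting in which they were tested (27 or 28 settings), while the calls of Cxcr2 and Apoe were lost without any single M0 array of either genotype. The count was 23, 18 and 18 without knockout M0 arrays a, b and c, 29, 30 and 25 without wild-type M0 arrays a, b and c, and 19 without the 3 arrays of lowest detected share.

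MHC class II genes were higher in knockout M0 cells, with 3 of 9 past the threshold (6 over the list alone; median 0.56 log2, or 0.44 with undetected genes at their bound; camera, adjusted p = 1.8e-10), namely H2-Aa, Cd74 (0.96 ± 0.145 log2) and H2-Ab1 (0.92 ± 0.157 log2). Of 4 measured markers of monocytes and interstitial macrophages, C1qb alone passed in the same direction (2 over the list alone; median 0.52 log2), and of 4 neutrophil markers Cxcr2 alone did (2 over the list alone; median 0.48 log2). NRF2 genes were lower, with 3 of 19 past the threshold (6 over the list alone; median -0.18, adjusted p = 3.17e-05), namely the glutathione transferase Gsta3 (-1.29 ± 0.206 log2), Gclm (-0.87 ± 0.158) and sulfiredoxin (Srxn1, -0.55 ± 0.1). The sign of Gsta3 turned (0.0334 log2) with no detection filter, where another probe stood for it. Genes next to Psmb8 on chromosome 17 were higher, with H2-Aa, H2-Ab1 and Psmb9 of 28 past the threshold (6 higher and 1 lower over the list alone; median 0.10, 0.08 at the bound, adjusted p = 0.0219, but 0.0621 with an estimated correlation). Cholesterol synthesis had 0 of 15 past the threshold (1 over the list alone; median 0.11, adjusted p = 0.0195, but 0.187 with an estimated correlation), and matrix protease and fibrosis-associated genes had Mmp13 of 14 lower (1 higher and 3 lower over the list alone; median -0.13, adjusted p = 0.0466, but 0.141 with an estimated correlation, 0.0557 with the replicate block on the authors' values, and 0.00346 to 0.283 over all settings run). The calls of Gclm, Srxn1, Gsta3, H2-Ab1, Cd74 and C1qb were lost in 12, 15, 6, 6, 4 and 3 of the other settings. The M2 marker list did not differ between genotypes in M0 cells past the threshold. However, 7 of its 23 members were undetected in both M0 groups and could not show a difference. Another 2 were undetected in 1 of these groups.

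After IL-4, the knockout cells had more of several M2 transcripts. Retnla was 2.98-fold higher than in wild-type M2 cells (1.57 ± 0.150 log2, adjusted p = 0.000296), with 8.27 ± 0.104 against 6.70 ± 0.327 log2 units (SD, n = 3). Cish (0.94 ± 0.107 log2) and Irf4 (0.78 ± 0.128 log2) were higher too. Arg1 and Ccl17 had differences of 0.56 ± 0.132 and 0.77 ± 0.191 log2 that missed the threshold (adjusted p = 0.0605 and 0.0670), and Chil3 was at the ceiling of intensity on all 3 knockout M2 arrays, so that probe was not compared, and its other probes differed by 0.15 and 0.0055 log2. The knockout cells had less H2-M2 (-4.27 ± 0.283 log2 in the model, but detected on 1 of 3 knockout M2 arrays, so that its level there is near background), Il7r (-2.72 ± 0.191), Ccl4 (-2.09 ± 0.257), Clec4d (-2.03 ± 0.147), Emp1, an epithelial membrane protein (-1.86 ± 0.142), Clec4e (-1.85 ± 0.148) and the cholesterol exporter Abca1 (-1.45 ± 0.250), and the heparan sulfate proteoglycan Gpc1 was at least 2-fold lower. Il1rn, the interleukin-1 receptor antagonist and a member of the M2 list, was lower as well (-1.42 ± 0.256 log2). By limma 134 genes passed, 44 higher and 90 lower, and the groups did not overlap for 19.2% of all genes, against 10% by chance.

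Of the 23 M2 markers 4 were higher and Il1rn lower in knockout M2 cells (8 and 1 over the list alone; median 0.24 log2; camera, adjusted p = 1.31e-06). With only probes detected at p under 0.01 on all 12 arrays this list call was lost (adjusted p = 0.0631, with 5.85e-09 to 0.0631 over all settings run). Markers undetected in M0 cells, such as Retnla, Cish and Irf4, drop out under that filter, so a smaller list was tested. Cholesterol synthesis genes were higher, with 5 of 15 past the threshold and 14 over the list alone (median 0.60, 0.55 at the bound, adjusted p = 1.67e-15), among them Nsdhl (0.75 ± 0.115 log2), Fdps (0.72 ± 0.154), squalene epoxidase (Sqle, 0.70 ± 0.122) and Idi1 (0.60 ± 0.120). Sqle fell with IL-4 in wild-type cells (-0.57 ± 0.122 log2), and Nsdhl rose in knockout cells (0.87 ± 0.115 log2). MHC class II genes were higher again, with 3 of 9 (7 over the list alone; median 0.62, adjusted p = 1.91e-07), H2-Eb1 by at least 2.02-fold, H2-Ab1 by 0.74 ± 0.157 and H2-Aa by 0.71 ± 0.104 log2, beside C1qb, at least 1.16-fold higher. Oxidative phosphorylation genes were shifted up together, with 33 of 34 estimates above 0 and 0 past the threshold singly (2 over the list alone; median 0.17, adjusted p = 7.53e-09). The calls of Fdps, Idi1, H2-Ab1 and H2-Eb1 were lost in 14, 9, 15 and 12 of the other settings. Ribosomal protein genes had 0 of 30 past the threshold (1 over the list alone; median 0.05, adjusted p = 0.0188, but 0.0567 with an estimated correlation).

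Lower in knockout M2 cells were the NRF2 genes, with 6 of 19 past the threshold (9 lower and 1 higher over the list alone; median -0.25, -0.24 at the bound, adjusted p = 8.21e-07). They included the cystine transporter Slc7a11 (-1.03 ± 0.178 log2), Gclm (-0.79 ± 0.158), Srxn1 (-0.65 ± 0.1) and thioredoxin reductase (Txnrd1, -0.55 ± 0.0906). Of 14 matrix protease and fibrosis-associated genes 4 were lower (5 over the list alone; median -0.28, -0.16 at the bound, adjusted p = 0.000147), namely Mmp13 (-1.85 ± 0.205 log2), Tgfbi (-0.56 ± 0.111), Adam17 (-0.51 ± 0.0993) and Mmp12 (-0.48 ± 0.0988). Tgfbi, Adam17 and Mmp12 lost their calls in 9, 8 and 14 of the other settings. Of 12 M1 inflammatory genes Ccl4 alone passed (1 higher and 3 lower over the list alone; median -0.30, -0.22 at the bound, adjusted p = 0.00116, but 0.0558 with an estimated correlation). Of 25 pattern recognition receptors 5 were lower, among them Clec4d, Clec4e, Marco (-1.14 ± 0.121 log2) and Clec4n (-0.78 ± 0.110 log2), but the list did not pass (median 0.00, adjusted p = 0.0711). With an estimated correlation 6 of the 8 list calls held, all but the ribosomal protein and M1 lists. The count of genes was 45, 51 and 70 without wild-type M2 arrays a, b and c, 72, 84 and 63 without knockout M2 arrays a, b and c, 47 with median scaling (11 higher, 36 lower) and 41 without the 3 arrays of lowest detected share. Psmb8, H2-M2, Il7r, Clec4d, Clec4e, Emp1, Gpc1, Marco, Mmp13, Retnla and Cish passed in every other setting in which they were tested (24 to 28 settings), and the other genes named for this contrast lost their calls in 1 (Ccl4, Clec4n), 2 (Nsdhl), 3 (H2-Aa), 4 (Abca1, Il1rn, Srxn1), 5 (C1qb, Slc7a11, Txnrd1), 6 (Irf4, Sqle) or 7 (Gclm).

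**Figure D3:**
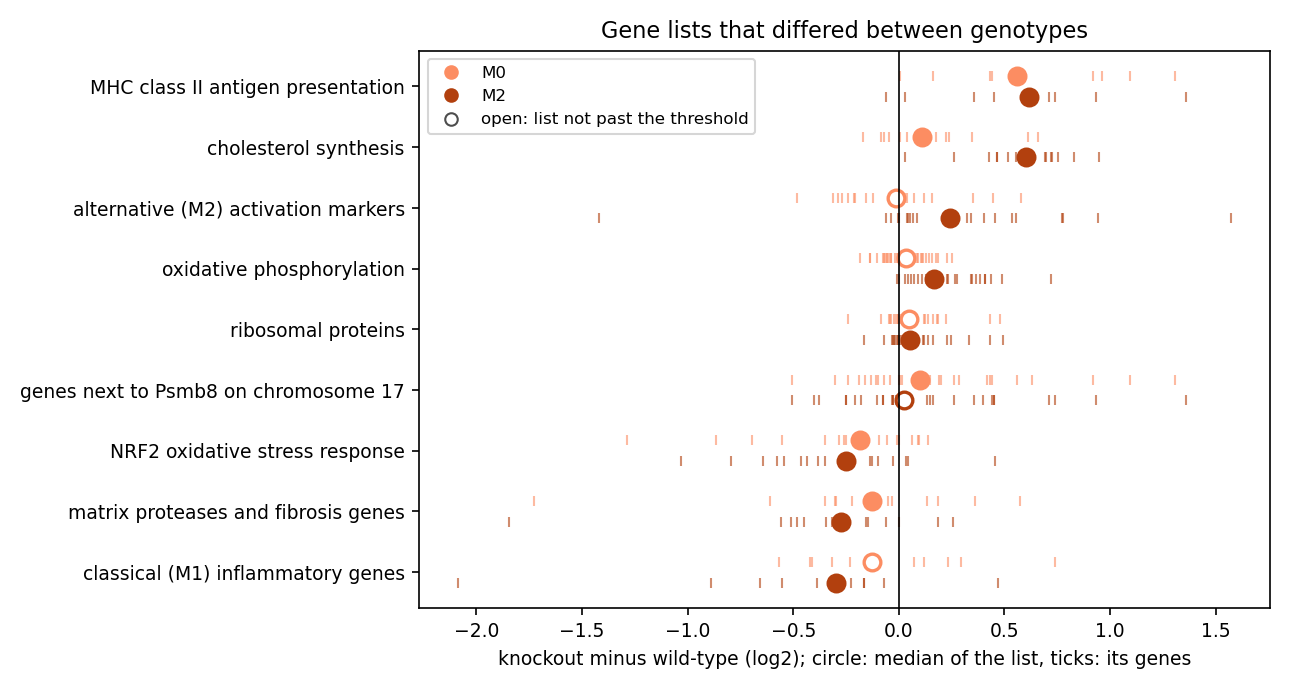
Knockout minus wild-type difference (log2, horizontal) for the 9 gene lists that passed the threshold between genotypes in M0 or M2 cells, with ticks for genes and circles for the list median, open where the list did not pass. MHC class II medians were 0.56 in M0 and 0.62 in M2 cells, while the cholesterol synthesis median was 0.11 in M0 and 0.60 in M2 cells.

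The genotype differences in M0 and M2 cells, which share no arrays, had 11 genes higher and 12 lower in both, against 0.168 and 0.274 for independent lists. Both contrasts use the same estimate of each gene's spread, so the lists are not fully independent. The shared higher genes included Cxcr2, Cyp4f18, C1qb, Dnajc15, the fatty acid binding protein Fabp5, H2-Aa, H2-Ab1 and H2-T24. The shared lower genes included Psmb8, H2-M2, Il7r, Ch25h, Emp1, Marco, Mmp13, Gclm and Srxn1.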

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

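Chosen only after the results were seen were the tests of the chromosome 17 neighbours, of Cd74, of the markers of other cell types, of a stretch of all responses and of the arrays of low detected share; the tests of other splits of the arrays and of single arrays were set before. Several results stand out because the IL-4 response differed between genotypes by a test of the difference itself. By gene these are Clec4d (-1.74 log2), Mamdc2 (-1.39), Pla2g7 (-1.23), Gpr65 (-1.10) and Fpr2 (-0.95), with negative differences (for Clec4d a deeper fall in knockout cells), and Retnla (1.5) and Cish (0.96), with positive ones. By list they are the medians of cholesterol synthesis (0.41 log2), M2 markers (0.36), oxidative phosphorylation (0.13), pattern recognition (-0.11) and M1 inflammatory genes (-0.17). The rest stand out because they lie outside the tests by gene. Of 574 kept probes without a gene name, 78 passed for IL-4 in wild-type cells (43 higher, 35 lower), 125 for IL-4 in knockout cells (60 higher, 65 lower), 4 between genotypes in M0 cells, 12 in M2 cells and 4 for the difference of the responses.

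Other splits of the same arrays were fitted with limma in the same way. For IL-4, the real split gave 1053 genes in wild-type and 1422 in knockout cells, and the highest other split gave 0 in either. Between genotypes, the real split gave 45 genes in M0 and 134 in M2 cells, and the highest other split gave 1 and 0. In each of these 4 comparisons 1 of 10 splits reached the real count, the real split itself, and 10 splits are too few for a share under 0.05. The other splits mix the real groups, so a real difference widens their spread, and their low counts do not measure the number of false calls. For the difference of the responses, 1 of 100 drawn splits reached the 7 genes, the real split itself, and the highest other gave 3. The drawn splits kept any real difference of the responses in their spread, so the same limit holds for their counts. By the share of drawn splits, chance can be excluded for the 7 genes only if the arrays of a state are exchangeable. The correlation of same-numbered samples leaves this in doubt, and no splits within pairs were drawn. The count was also 0 without array b of knockout M0, array a of knockout M2 or array a of wild-type M2 cells (385, 410 and 362 genes at an unadjusted p under 0.05).

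The first pattern is the genotype difference in MHC genes, to which DNA of another strain carried along with the knockout allele may contribute, since 9 of 80 measured neighbours of Psmb8 (11.2%) passed for the mean genotype effect against 3.13% of other genes (one-sided Fisher exact test, p = 0.00103). Without the class II genes, Psmb9, Tap1 and Tap2 the excess by the same exact test was not seen within 40 neighbours on each side (3 of 72, p = 0.396) but was within 60 (8 of 112, p = 0.0243), where H2-M2, H2-T10, H2-T24 and Pla2g7 enter. Cd74, which does not lie on chromosome 17, had a mean genotype effect of 0.79 log2. This argues against linked DNA that acts only on genes beside it as the whole cause of the class II difference. Linked DNA that acts on genes elsewhere stays open. More interstitial macrophages or dendritic cells in the knockout lavage cannot be told apart from a change in the macrophages, since Cx3cr1, Flt3, Zbtb46 and Ccr7 were undetected on all arrays and the median of 0.107 log2 (SE 0.161) over 7 markers is that of Zbtb46, and a direct effect of Lmp7 loss stays open as well. The other 3 markers all had positive estimates. C1qb was higher (at least 1.64-fold in M0 and 1.16-fold in M2 cells). C1qc, detected on all 3 knockout M0 arrays but 1 of 3 wild-type M0 arrays, had a mean genotype effect of 0.66 ± 0.12 log2, which includes values near background. That of C1qa, detected on 1 or 2 arrays of each group, was 0.16 ± 0.254 log2.

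The second pattern is the larger IL-4 response of M2 markers in knockout cells. A single array as the cause is argued against, since the median difference stayed at 0.28 log2 or above without any 1 of the 12 arrays. A stretch of all responses, by scaling or by array quality, cannot be told apart from a response of these markers alone. The slope of the knockout on the wild-type response was 1.203 over 19 induced M2 markers and 1.105 over the 986 other induced genes, inside the range of random sets of the latter (0.838 to 1.39) but at the upper limit of sets matched on the size of the response (1.023 to 1.203, with 2.59% of sets as high), for which only 10 genes stood against the 7 markers above 2 log2 units. A stronger response of knockout cells to IL-4 as a whole, which is biological and would stretch all responses in the same way, stays open.

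The third pattern is the 10 members of the pattern recognition, M1 and matrix lists that were lower in knockout M2 cells, among them Clec4d, Clec4e, Marco, Mmp13 and, as the only chemokine, Ccl4. They were picked by these calls, so their median of -0.961 log2 describes them and tests nothing, and over all members the lists had medians of 0.00, -0.30 and -0.28 log2. Fewer neutrophils in the knockout lavage stays open. Neither of the 2 neutrophil markers detected on all 3 wild-type M2 arrays was lower (S100a8 0.16 ± 0.152 log2, Cxcr2 1.86 ± 0.272). However, S100a8 fell and Cxcr2 rose with IL-4 in both genotypes, so their levels need not follow neutrophil number. Other neutrophil markers, among them S100a9, Mpo, Elane, Ltf and Ngp, were undetected on all arrays. Fewer monocytes stays open too, since 0 of 5 monocyte markers were detected on all 3 wild-type M2 arrays. Arrays of low detected share cannot be told apart from an effect of genotype, since the median without the 3 lowest (-0.996 log2) was taken over the same picked genes and of these arrays only knockout M2 a enters the contrast, although Clec4d, Clec4e, Marco and Mmp13 kept their calls without it. An effect of genotype on the macrophages was not tested further and stays open, as does a difference between the mice other than Lmp7.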

How the results depend on the processing

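Chosen only after the data were seen were the replicate blocks on the authors' values, the fit without the 3 arrays of lowest detected share and that share as a covariate; the other 26 settings were planned. With median scaling 469 genes passed for IL-4 in wild-type and 750 in knockout cells, 24 and 47 between genotypes in M0 and M2 cells, and 1 for the difference of the responses. With only the 2 groups compared 14 genes passed in M0 and 45 in M2 cells. With trended and robust variances 109 passed in M0 cells, 277 in M2 cells and 24 for the difference. At an adjusted p under 0.10, 241 passed in M2 cells and 14 for the difference. With probes detected at p under 0.01 on all 12 arrays 212 passed in M2 cells. Without the 3 arrays of lowest detected share 19 passed in M0 and 41 in M2 cells and, by limma, 0 for the difference (492 at an unadjusted p under 0.05). With the replicate block on the authors' values 212 passed in M2 cells, and with the block within genotype 11 for the difference. The authors' values alone gave 1116, 1505, 48, 171 and 5 genes in the 5 contrasts. Leaving out single arrays gave 18 (without knockout M0 b or c) to 41 genes (without knockout M2 a) in M0 cells, 45 (without wild-type M2 a) to 111 (without knockout M0 a) in M2 cells, and 0 (without knockout M0 b, knockout M2 a or wild-type M2 a) to 8 (without wild-type M0 b) for the difference. Fry called 72 lists over all contrasts, against 40 by camera. With no detection filter another, brighter probe stood for Gsta3, whose values became 0.28 log2 for IL-4 in wild-type cells and 0.0334 between genotypes in M0 cells. The cause of the other shifts was not tested.

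Replicate numbers did not pair wild-type M0 with wild-type M2 samples (r of 0.15, -0.00978 and 0.0698) or wild-type M2 with knockout M2 samples (0.122, -0.0178 and 0.054). The authors' values alone ended the calls of Retnla and Cish for the difference (adjusted p = 0.179 and 0.0912), which stayed lost with the replicate block (0.157 and 0.0918). Ccl17 in M2 cells passed with the block (0.0259) and not with those values alone (0.0676), within 0.00936 to 0.385 over all settings run. Probes detected on fewer than 3 arrays were not tested, so genes of low level are missing from every count.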

Other observations

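The tests reported in this part were planned. The lists of the immunoproteasome, MHC class I presentation and IL-4 receptor signalling passed in no contrast. The immunoproteasome list, of 5 measured genes, had a median of 0.05 log2 between genotypes in M0 cells (Psmb9 higher, Psmb8 lower; camera, adjusted p = 0.827) and 0.10 in M2 cells (adjusted p = 0.699). Of 12 genes of MHC class I presentation 0 passed between genotypes by limma in either state (list adjusted p = 0.542 and 0.607). Of 14 genes of IL-4 receptor signalling, Cish and Irf4 were higher in knockout M2 cells (list median 0.04 log2, adjusted p = 0.147), while in wild-type cells IL-4 raised Cish, Irf4 and Jak2 and lowered Ptpn6 and Stat3 (adjusted p = 0.506). Of 13 interferon-induced genes, the list median was 0.20 log2 in M0 and 0.19 in M2 cells (0.08 at the bound in M2), not past the threshold (adjusted p = 0.0852 and 0.341). Of 22 alveolar macrophage identity genes, Fabp5 was higher and Marco lower in knockout cells of both states (Fabp5 lost its call in 9 of the other settings in M0 and 7 in M2 cells), and Gpnmb lower in M2 cells (a call lost in 7; -0.63 ± 0.119 log2, and -0.48, -0.95 and -1.48 by its dimmer probes). The identity list did not pass (median 0.01 and -0.05 log2, adjusted p = 0.831 and 0.0727).

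Other lists without a call in any contrast were ubiquitin genes and deubiquitinases, fatty acid metabolism, glycolysis, chemokine and cytokine receptors, and apoptosis with p53 targets. Their adjusted p for IL-4 was 0.911, 0.641, 0.593, 0.073 and 0.181 in wild-type cells and 0.838, 0.77, 0.621, 0.0711 and 0.104 in knockout cells. Between genotypes it was 0.276, 0.608, 0.523, 0.494 and 0.516 in M0 cells and 0.0875, 0.367, 0.766, 0.969 and 0.804 in M2 cells. The chemokine and cytokine receptor list had 5 of 18 genes lower and 3 higher in wild-type cells after IL-4, and 9 lower and 2 higher in knockout cells. Markers of other cell types were few: 4 of 14 listed for monocytes and interstitial macrophages were measured, 2 of 11 for dendritic cells, 4 of 13 for neutrophils, 0 of 10 for B cells and 3 of 17 for T and NK cells. After IL-4, Cd14 alone of the 4 monocyte and interstitial macrophage markers was lower in either genotype (medians -0.30 log2 in wild-type and -0.48 in knockout cells; 1 and 3 lower over the list alone). Its call in wild-type cells (limma, adjusted p = 0.0494) was lost in 12 of 24 other settings. Cd14 was detected on 1 wild-type M0 array, 2 knockout M0 arrays and 0 M2 arrays, so its values lay near background. Of the 4 neutrophil markers S100a8 and Csf3r were lower and Cxcr2 higher in either genotype (medians -0.15 and -0.63 log2). A dimmer probe stood for Csf3r, since its brightest was detected on only 1 array, of knockout M0 cells. The Csf3r call was lost in 1 of 27 other settings in each genotype (limma, adjusted p = 0.736 in wild-type and 0.826 in knockout cells).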
